A study of Gallus gallus with 6 samples.

How the data were processed

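Bulk RNA-seq was done on total RNA of chicken ovarian cancer cells from ascites, with 125 bp paired-end reads per the labels. The labels give 3 primary lines, each cultured to confluence, dissociated with trypsin and sorted by FACS for ALDH activity, and 1 library per line and fraction. The lines are treated as independent replicates because the labels give them separate names. P-values therefore measure the spread between these samples. How ALDH activity was measured and where the gate was set, and any gate other than ALDH, are not given in the sources used here.

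The submitters' notes name FastQC and Trimmomatic for read checks and trimming, HISAT2 and kallisto for alignment and quantification, DESeq2 for testing and the GRCg6a genome build, without versions. The authors deposited estimated counts (expected counts) per transcript, of which 42.2% of the positive values are whole within 0.001. The authors also deposited TPM (transcript abundance scaled by effective length and to a common total). The deposited comparison table holds a signal per library, the estimated count divided by a size factor, and its means per group. The same table, as deposited by the authors, holds a ratio (ALDH+ over ALDH-), log2 fold changes with their SE, a Wald score, an expected number of false positives as another score, and p-values (unadjusted, adjusted and as a false discovery rate). Transcript lengths, an other kind of value, are given per the file headers. Deposited TPM and TPM recomputed from the one deposited length column had median ratios of 1.0 to 1.033 per library.

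The 28756 transcripts were summed to 16963 genes by the deposited gene ID and rounded. Of these genes 12462 have a name, 17 names belong to more than 1 gene ID, and 6155 genes have more than 1 transcript. Transcripts without a gene ID (319) hold 0.28 to 0.33% of counts and were left out of the gene counts. The deposited IDs belong to another genome build than the reference table at hand, where 0 matched by ID and 11864 gene names were found as symbols, so no positions are given. Reads shared between paralogs cannot be traced in these tables.

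Group comparisons used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr by group with a minimum count of 10 and a minimum total of 15), with Benjamini-Hochberg adjusted p under 0.05 as the threshold, two-sided. Adjusted p values in the text are from edgeR for genes and from limma 3.58.1 (camera, on log2 CPM with a prior count of 2) for lists unless another tool is named. A count adjusted over the list alone uses the same unadjusted p values corrected within the list. Errors of log2 changes are standard errors derived from the F statistic, and ± gives the SD over 3 libraries. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so model-based tests were used. TMM factors were 1.044, 0.954 and 0.832 in the ALDH- and 1.118, 1.002 and 1.077 in the ALDH+ libraries of C27, C29 and C30.

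Both fractions of a line share 1 cell line, which the labels state in naming the line and the replicate number, so the design is paired and a fit with the line as a block is given beside the fit without it. As a check, the deviations of the ALDH+ and ALDH- library of a line from their group means correlated across genes at r = 0.66, 0.17 and 0.49 for C27, C29 and C30. The block called 1732 genes against 786 without it. The common dispersion was 0.152 without and 0.077 with the block. Lines were compared by an F test of the line terms with the fraction in the model.

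Gene lists (33, each with at least 5 tested members) were written, and comparisons, alternatives and the rule for naming genes chosen, before the data were examined. The lists cover ALDH genes, stemness, epithelial, mesenchymal, ovarian and oviduct markers, the retinoic acid, Wnt, Notch, Hedgehog and TGF-beta pathways, detoxification, DNA replication, mitosis, DNA repair, glycolysis, oxidative phosphorylation, unfolded protein response, cholesterol synthesis, interferon and inflammatory genes, heat shock, apoptosis and matrix genes, markers of fibroblasts, macrophages, lymphocytes, heterophils, erythroid, endothelial, mesothelial and granulosa cells, ribosomal proteins and mitochondrial transcripts. A further 2 lists (focal adhesion and actin, lysosome) were written after the data were examined, and their test values were adjusted over these 2 lists alone. Camera used a preset correlation of 0.01, beside an estimated correlation and fry. The rule names ALDH1A1, ALDH1A2 and ALDH1A3, the 12 highest and 12 lowest log2 changes among named genes that passed with a mean CPM of at least 1 and the same side in all 3 lines, up to 4 members per list with the smallest unadjusted p in the blocked fit, and 5 genes per line. Other genes in the text were chosen after their values were seen.

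Alternatives were DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1 (TPM of at least 1 in 3 libraries, or no filter), other scaling factors, no filter or a mean CPM of at least 5, and leaving out each library or line in turn. Transcripts in place of genes and a scaling that holds fibroblast markers at a median change of 0 were added later. On simulated data with 200 changed genes, edgeR without the block recovered 0% of 2-fold, 49.3% of 4-fold and 77.3% of 8-fold changes with 0% false calls. With the block it recovered 23.9, 86.6 and 100%, with 8.5% of calls on unchanged genes. DESeq2 recovered 6, 80.6 and 92.4% without and 35.8, 86.6 and 100% with the block, with 1.7 and 13.5% of calls on unchanged genes, and limma-voom 0, 41.8 and 71.2% without and 23.9, 88.1 and 100% with it, with 0 and 10.2%. The line test recovered 99.5% of 8-fold changes with 7.6% false calls. Raising 62 ribosomal genes 2-fold gave camera an adjusted p = 2.5e-75, and an adjusted p = 0.188 with an estimated correlation, with 0 other lists called at the preset correlation. That 0 does not show how often camera calls lists wrongly on the real data. Correlations estimated there ran from -0.093 (endothelial markers) to 0.96 (mitosis), against the preset 0.01. Splits of the libraries into 3 and 3 other than the real one called 4 to 14 lists at the preset correlation. Tables were summed in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9. Raw reads, lengths of single isoforms and protein levels were not analysed here.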

Results

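RNA was sequenced from chicken ovarian adenocarcinoma cells that had been grown from ascites fluid. The cells came from 3 primary lines, C27, C29 and C30, which are replicates 1, 2 and 3. Each confluent culture was separated by flow cytometry on aldehyde dehydrogenase (ALDH) activity, a property widely used to enrich tumour cells with stem-like behaviour, into an ALDH+ and an ALDH- fraction. This gave 6 libraries in groups of 3. Estimated counts totalled 25383715, 22926423 and 24208916 in the ALDH- libraries of C27, C29 and C30, and 26747453, 22170788 and 23065338 in the ALDH+ libraries. After low counts were filtered out, 12811 genes were tested. On the first principal component, which held 57.3% of the variance, the ALDH+ libraries lay together at 65, 59.3 and 57.4, while the ALDH- libraries lay at -28.7, -57.9 and -95, with C30 farthest out. On the second (24.2%), the ALDH+ libraries of C27, C29 and C30 lay at 26.1, 21.9 and -72.3, with C30 apart. The ALDH- libraries lay there at 56.3, -7 and -24.9.

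The main question was which genes differ between cells with high and low ALDH activity, and the ALDH genes themselves come first. ALDH1A3 (ENSGALG00000033365), which makes retinoic acid from retinal, rose from 115.8 ± 46.8 CPM (counts scaled to library size; mean and SD, n = 3) in ALDH- to 369.2 ± 75.1 in ALDH+ cells. Its log2 fold change in edgeR was 1.67 (SE 0.33, adjusted p = 0.0228), and it was higher in ALDH+ in 3 of 3 lines. ALDH1A1 (ENSGALG00000015147), the isoform most often tied to this sort in human cells, stood at 2.92 ± 0.99 and 6.16 ± 6.58 CPM (log2 1.08, SE 0.74, adjusted p = 0.453). The higher ALDH+ mean of ALDH1A1 came from C27, at 13.7 CPM. ALDH1A2 (ENSGALG00000004270) stood at 5.57 ± 0.83 and 4.34 ± 0.44 CPM (log2 -0.36, SE 0.32, adjusted p = 0.57). ALDH1A3 was the only 1 of 11 measured ALDH genes that changed, both over all genes tested and adjusted over the list alone. The list as a whole had a median log2 change of -0.17 and a mean of 0.18 (camera direction up, adjusted p = 0.725), and its median became 0.24 on the TPM scale (log2 TPM). The call of ALDH1A3 ended without the ALDH- library of C29 (adjusted p = 0.102) or C30 (0.0889), and without the ALDH+ library of C27 (0.0705) or C30 (0.0616). It also ended when libraries were scaled to fibroblast markers (log2 0.83, adjusted p = 0.0686).

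Across all genes, 786 differed between the fractions (edgeR, adjusted p under 0.05), 107 higher and 679 lower in ALDH+ cells. Changes of at least 4-fold numbered 22 upward and 548 downward. The median log2 change was 1.55 among the genes that rose and -3.52 among those that fell. Rankings here take only called genes with a name, a mean CPM of at least 1 and the same side in all 3 lines. Within these limits, the 12 genes that rose most were EPAS1, ITGA8, TRPC4, RELN, EDN2, PDLIM3, GABRA4, MOXD1, VCL, EDN1, ITGA9 and CCDC170, with log2 changes from 2.94 to 2.12. VCL encodes vinculin, a linker between integrin adhesions and actin, and rose from 67.2 ± 19.8 to 323.1 ± 68.2 CPM (n = 3; log2 2.27, SE 0.30, adjusted p = 0.00388). The integrin gene ITGA8 rose by 2.82 (SE 0.61, adjusted p = 0.0325), ITGA9 by 2.17 (SE 0.39, adjusted p = 0.015), and EPAS1, a hypoxia-inducible transcription factor, by 2.94 (SE 0.65, adjusted p = 0.0346). Within the same limits, the 12 that fell most were KMO, LYZ, S100A12, P2RY13, CSTA, ADORA3, MLKL, P2RY6, VSIG4, S100A16, GSTA3 and TREM-B2, with log2 changes from -6.72 to -5.89. CSTA, a cysteine protease inhibitor, fell from 2348 ± 1490 to 35.7 ± 7.98 CPM (n = 3; log2 -6.04, SE 0.62, adjusted p = 0.00155). KMO, a kynurenine pathway enzyme, had 381 counts over the 3 ALDH- libraries and 4 over the 3 ALDH+ libraries. The genes that fell made up 12.9, 13.4 and 19.1% of all counts in the ALDH- libraries of C27, C29 and C30, and 2.67, 2.49 and 1.66% in the ALDH+ libraries.

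The ALDH+ and ALDH- libraries of a line come from the same culture, and a fit with the line as a block called 1732 genes, 758 higher and 974 lower in ALDH+. All 786 genes called without the block were among them, in the same direction. The share of called genes that were higher in ALDH+ was 13.6% without the block and 43.8% with it. Without the block it was 34.7% on log2 TPM. With the block it was 54.2% with upper quartile factors, 57.8% with library size only and 76% on log2 TPM. Of all genes tested, 3301 (25.8%) had no overlap between the 3 ALDH+ and the 3 ALDH- libraries. Exchangeable libraries would give 10% on average, a value that ignores the pairing and the correlation between genes. The share in other splits was not counted. In the fit without the block, the number of genes higher in ALDH+ varied with the library left out. It was 370, 13 and 13 without the ALDH- library of C27, C29 or C30, and 42, 50 and 44 without the ALDH+ library of C27, C29 or C30. Of the 107 genes, 84, 10, 12, 35, 34 and 35 kept their calls in these fits, in the same order. With the block, the number higher was 454, 1096 and 502 without the ALDH- library of C27, C29 or C30. It was 394, 1028 and 356 without the ALDH+ library of C27, C29 or C30. Calls of single genes lost without a library are from the fit without the block throughout. The total of 786 fell to 443 without the ALDH- library of C30, 502 without the ALDH+ library of C27 and 475 without the ALDH+ library of C29. Of the 12 genes that rose most, VCL alone stayed called without each library in turn (adjusted p from 0.00376 to 0.0231), and the other 11 reached adjusted p values up to 0.18. Of the 12 that fell most, 9 stayed called throughout. LYZ lost its call without the ALDH+ library of C29 (adjusted p = 0.0538), and S100A12 and MLKL lost theirs without the ALDH+ library of C27 or C29 (up to 0.0725 and 0.0854).

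Macrophage and monocyte markers were far lower in ALDH+ cells. Of 23 measured macrophage and monocyte markers, 20 fell and 22 fell adjusted over the list alone, with a list median of -4.63 on the log2 scale. SPI1, the transcription factor PU.1 of myeloid cells, fell from 266 ± 96.3 to 8.36 ± 2.01 CPM (n = 3; log2 -4.99, SE 0.37, adjusted p = 0.0011). The scavenger receptor gene MARCO fell from 2474 ± 1460 to 42.3 ± 17.9 CPM (log2 -5.87, SE 0.61, adjusted p = 0.00155), and LCP1, a leukocyte actin-bundling protein gene, from 680 ± 285 to 17.9 ± 7.2 CPM (log2 -5.25). CD74 (-2.10, adjusted p = 0.0718) and the class II gene BLB1 (-2.97, adjusted p = 0.0845) did not pass, and BLB1 has close paralogs whose reads are hard to separate. MRC2 stood at 1.24 (adjusted p = 0.329), and with the line as a block it rose by 1.39 (adjusted p = 0.00733). The macrophage list gave an adjusted p = 5.3e-22 in camera and an adjusted p = 0.24 with an estimated correlation. With an estimated correlation camera called 0 of the 33 lists. It also missed a simulated 2-fold rise of 62 ribosomal genes (adjusted p = 0.188). That list has a high estimated correlation in the real data (0.87, against 0.37 for the macrophage list). How often lists of lower correlation are missed was not simulated. With 0 lists called, that setting does not separate 1 list from another. The macrophage list's genes held 0.693, 0.568 and 0.975% of counts in the ALDH- libraries of C27, C29 and C30, and 0.0653, 0.0443 and 0.0312% in the ALDH+ libraries.

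Among 7 measured heterophil and mast cell markers, 4 fell and 6 fell adjusted over the list alone. They included the granulocyte receptor gene CSF3R (-4.78, adjusted p = 0.00178), KIT (-4.65, adjusted p = 0.00339), the lysozyme gene LYZ (-6.67) and S100A12 (-6.67), which stood at 2516 ± 2750 CPM in ALDH- cells. The count was 2 without the ALDH+ library of C29. Of 12 measured lymphocyte markers, 5 fell, also adjusted over the list alone. These were IKZF1 (-4.96), PTPRC (-3.32), IL2RG (-5.25), BLK (-5.42) and CD5 (-5.34), of which PTPRC encodes the pan-leukocyte antigen CD45. The T cell receptor genes CD3E (1.29, adjusted p = 0.197) and CD3D, and LCK, did not pass. Of 6 measured erythroid and thrombocyte markers, TAL1 fell (-4.92) and the other 5 did not pass, while 2 fell adjusted over the list alone and 2 with the block. The camera test called the heterophil (median -4.65, adjusted p = 8.82e-05) and lymphocyte lists (median -0.39, adjusted p = 0.00705), with adjusted p = 0.24 and adjusted p = 0.381 with an estimated correlation. On log2 TPM the lymphocyte median was -1.47, and with no filter on low counts the heterophil median was -2.08. The erythroid list (median -0.76, adjusted p = 0.21) was called only without the ALDH+ library of C30 (-1.04, adjusted p = 0.026).

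**Figure D1:**
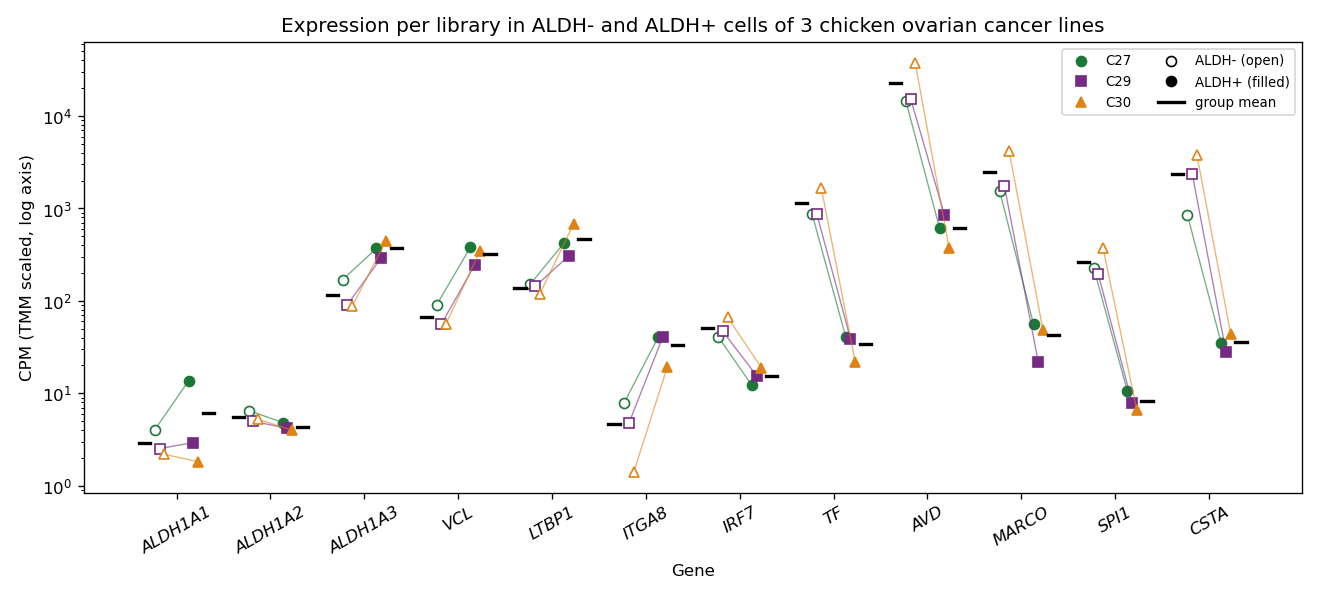
CPM (TMM scaled, log axis) of 12 genes in the 6 libraries, with open symbols for ALDH-, filled symbols for ALDH+, a shape and colour per line, thin lines joining the libraries of a line and bars at group means. MARCO, SPI1 and CSTA are more than 16-fold lower in ALDH+ cells, VCL rises from a mean of 67.2 to 323.1, and ALDH1A1 is apart in C27 ALDH+ at 13.7.

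In groups tied to matrix and signalling most measured members had a log2 change above 0 under TMM scaling but few were called, and the camera calls of these lists did not hold with an estimated correlation (adjusted p = 0.24 to adjusted p = 0.49). The macrophage list moved the other way, at a median of -4.63. Extracellular matrix genes took 7.44, 4.8 and 3.04% of counts in the ALDH- libraries of C27, C29 and C30 and 11.2, 11 and 8.32% in the ALDH+ libraries. Of 47 measured matrix genes, 1 rose and 2 fell over all genes tested, and 9 rose and 2 fell adjusted over the list alone. With the line as a block 20 rose and 3 fell. Tenascin C (TNC) rose by 1.38 (adjusted p = 0.0254), while osteopontin (SPP1, -5.86, adjusted p = 0.0175), a secreted protein that macrophages also make, and the laminin gene LAMA3 (-1.35, adjusted p = 0.0254) fell. Fibronectin (FN1) stood at 13110 ± 2290 and 30320 ± 2850 CPM (log2 1.21, adjusted p = 0.099), and lumican (LUM) at 1.98 (adjusted p = 0.0553, and 0.00229 with the block). Of 22 measured mesenchymal markers, TNC and TGFB3 (1.09, adjusted p = 0.0392) rose, and 8 rose adjusted over the list alone, with 5 rising and 1 falling in the blocked fit. No fibroblast marker of 12 passed in edgeR, although 1 rose adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 called 2 higher and limma-voom 0. With the block, LUM, MFAP5, PDGFRA and PDGFRB rose. The call of TNC ended without the C29 or the C30 library of either fraction (up to 0.0847), and SPP1 lost its call without the ALDH+ library of C27 or C29 (up to 0.0806). TGFB3 stayed called only without the ALDH- library of C27 (otherwise up to 0.158).

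The TGF-beta and BMP pathway had 24 measured members, of which 3 rose (4 adjusted over the list alone, 7 with the block). These were TGFB3, follistatin (FST, 1.17, adjusted p = 0.0211) and LTBP1, which holds latent TGF-beta in the matrix and went from 138 ± 17.7 to 471 ± 191 CPM (n = 3; log2 1.77, SE 0.33, adjusted p = 0.0175). The pathway count was 0 in edgeR without the ALDH- library of C29 or of C30, where 6 and 8 members were higher at an unadjusted p under 0.05 and no other tool was run, 1 without the ALDH+ library of C29 or C30, and 2 without that of C27. Of 24 measured Wnt pathway genes, the secreted Wnt inhibitor FRZB rose (1.27, adjusted p = 0.0186), 1 gene also adjusted over the list alone and 4 with the block. Of 11 Hedgehog pathway genes, the transcription factor GLI2 rose (1.16, adjusted p = 0.0469), with 2 adjusted over the list alone and 3 with the block. FRZB lost its call without either C29 library or the ALDH- library of C30 (up to 0.0713), and GLI2 without any library but the ALDH- library of C27 (up to 0.188).

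In camera, the median log2 changes and adjusted p values of these lists were 1.07 and 1.23e-07 for matrix, 0.72 and 0.000395 for mesenchymal markers, 0.81 and 0.00705 for fibroblast markers, 0.87 and 0.000951 for TGF-beta, 0.84 and 0.00207 for Wnt, and 0.55 and 0.00949 for Hedgehog. None held its call with an estimated correlation, with adjusted p = 0.466 for matrix, adjusted p = 0.381 for mesenchymal markers, adjusted p = 0.466 for fibroblast markers, adjusted p = 0.381 for TGF-beta, adjusted p = 0.24 for Wnt and adjusted p = 0.49 for Hedgehog. That setting called 0 of the 33 lists, so it cannot separate these lists from the rest. Fry called mesenchymal markers and Wnt up (adjusted p = 0.0225 each), and Wnt also with the block (0.0431). It did not call matrix, fibroblast, TGF-beta or Hedgehog genes (adjusted p from 0.0577 to 0.108). The camera call of Hedgehog genes also ended without the ALDH+ library of C27 (adjusted p = 0.0603). When the libraries were scaled so that fibroblast markers had a median change of 0, which moved the median of all genes to -0.84, the matrix median went from 1.07 to 0.34, and the medians turned to -0.12 for mesenchymal markers, -0.04 for TGF-beta, -0.06 for Wnt and -0.16 for Hedgehog. This follows from the shift of all genes. Camera compares a list with the other genes, so a list can stay called under a shift common to all genes. Its values still changed with this scaling, which ended 4 list calls, such as lymphocyte markers (adjusted p = 0.00705 to 0.196), and added 2. It still called up matrix (adjusted p = 2.64e-15), mesenchymal markers (0.000164), TGF-beta (2.86e-06), Wnt (0.000493) and Hedgehog (0.0254). Those calls come from the same libraries and are no added evidence. The fibroblast list itself, held at a median of 0, was also called (camera adjusted p = 0.000297). That scaling was chosen after the data were examined, and with it 33 genes were higher and 5753 lower in ALDH+ (0.6% higher).

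Markers of the tumour and of stem-like cells did not move as groups in camera. Of 10 measured ovarian carcinoma and oviduct markers, 2 fell, also adjusted over the list alone, and with the block 2 rose and 2 fell. The ones that fell were the egg-white protein genes AVD (avidin), from 22510 ± 13100 to 612 ± 244 CPM (n = 3; log2 -5.20, SE 0.61, adjusted p = 0.00229), and TF (ovotransferrin), from 1136 ± 445 to 33.8 ± 10.4 CPM (log2 -5.07, SE 0.43, adjusted p = 0.0011). Mesothelin (MSLN, 0.04, adjusted p = 0.985) did not differ detectably. This list had a median of 0.21, a mean of -0.61 and a camera direction of down (adjusted p = 0.55). Fry called it down (adjusted p = 0.0112), but not with the block (0.125). Of 14 measured stemness markers, KIT and the efflux pump gene ABCG2 (-2.55, adjusted p = 0.0376) fell, while MYC (0.29, adjusted p = 0.505), BMI1 (0.10, adjusted p = 0.814), CD44 (-0.62, adjusted p = 0.556) and PROM1 (-1.54, adjusted p = 0.153) did not pass. Adjusted over the list alone 1 rose and 2 fell, with the block 1 rose and 3 fell, and the list median was 0.14, its mean -0.30 and its camera direction down (adjusted p = 0.806). AVD, TF and KIT fell beside the macrophage list (median -4.63), and KIT is also on the heterophil and mast cell list (median -4.65). Which cells these falls came from was not tested. NANOG and LIN28B had no counts. ABCG2 stayed called only without the ALDH- library of C27 (otherwise up to 0.146). With the scaling to fibroblast markers the median was -0.82 for the ovarian and -0.65 for the stemness list.

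Of 13 measured epithelial markers, E-cadherin (CDH1, -4.08, adjusted p = 0.0471) fell and the other 12 did not pass. Adjusted over the list alone 2 rose and 1 fell, and with the block 4 rose, among them the desmosome gene DSP (1.80, adjusted p = 0.00542), and 1 fell. The epithelial median was 0.94 (camera adjusted p = 0.0516), called with the block (adjusted p = 0.0141, and adjusted p = 0.539 with an estimated correlation) and without the ALDH+ library of C30 (1.17, adjusted p = 0.0119). CDH1 lost its call without the ALDH- library of C30 or any ALDH+ library (up to 0.15). Of 20 measured retinoic acid pathway genes, ALDH1A3 rose and RBP7, a retinol-binding protein gene, fell (-4.79, adjusted p = 0.0116), likewise adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.41). Of 19 Notch pathway genes, RBPJ (-2.06), the glycosyltransferase gene MFNG (-5.26) and DTX1 (-3.74) fell, and adjusted over the list alone 4 rose and 4 fell. With the block 4 Notch genes rose and 3 fell, and without the ALDH- library of C27 3 rose and 2 fell. The Notch median was 0.26, its mean -0.05 and its camera direction up (adjusted p = 0.4). DTX1 rested on 64 counts in ALDH- and 5 in ALDH+ libraries, and stayed called only without the ALDH+ library of C30 (otherwise up to 0.09). Without the ALDH+ library of C29, RBP7 (adjusted p = 0.0652) and RBPJ (0.0534) lost their calls and 1 Notch gene fell. Scaled to fibroblast markers, the medians were 0.08 for epithelial, where the list was called up (adjusted p = 0.00101), -0.55 for retinoic acid and -0.58 for Notch genes.

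Some genes of detoxification and of immune signalling fell in ALDH+ cells, most members of these lists not passing. Of 33 measured drug efflux and detoxification genes, 7 fell (8 adjusted over the list alone), and with the block 2 rose and 10 fell. The glutathione transferase genes MGST2 (-4.86) and GSTA3 (-5.91) fell most, MGST1 fell from 733.9 ± 405 to 135.3 ± 60.3 CPM (n = 3; log2 -2.44, SE 0.49, adjusted p = 0.0247), and NFE2L2, the transcription factor of the oxidant response, fell by 1.17 on the log2 scale (adjusted p = 0.0304). The pump gene ABCC5 (-1.22) lost its call without the ALDH- library of C30 or the ALDH+ library of C27 (up to 0.058). The detoxification count was 3 and 2 without the ALDH- library of C29 or C30, and 2, 4 and 3 without the ALDH+ library of C27, C29 or C30. Of 28 interferon response genes, IFIT5 (-2.80, adjusted p = 0.0017), ZNFX1 (-2.58), IRF7 (-1.72, adjusted p = 0.0119) and IRF8 (-1.43) fell, 4 also adjusted over the list alone. The interferon count was 1 without the ALDH- library of C30 or the ALDH+ library of C27, and 2 without the ALDH+ library of C29. In these fits IRF7 reached adjusted p values up to 0.0561 and ZNFX1 up to 0.105, and IRF8 stayed called only without the ALDH+ library of C29 (otherwise up to 0.139). Camera gave a median of -0.55 and adjusted p = 0.00102 for detoxification (adjusted p = 0.458 with an estimated correlation), and -0.46 and adjusted p = 0.00949 for interferon (adjusted p = 0.381 with an estimated correlation). On log2 TPM the medians were -0.16 and -0.01, both lists still called. The macrophage list moved with both, at -4.63.

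Of 30 measured inflammatory cytokines and NF-kB targets, 5 fell, and adjusted over the list alone 1 rose and 5 fell. IL15 (-4.32, adjusted p = 0.0017), LITAF (-4.72, adjusted p = 0.00147), the chemokine gene CCL4 (-5.24, adjusted p = 0.0314; 1 of several IDs of that name), TNFRSF1B (-3.06, adjusted p = 0.0126) and NFKBIE (-1.95, adjusted p = 0.0431) fell. With the block 2 rose and 9 fell, including IL1B (-3.75, adjusted p = 0.000766; without it -3.98 and 0.151). The inflammatory median was -0.23 and turned to 0.13 on log2 TPM, below the median of all genes on that scale (0.36). Fry called the list down with the block (adjusted p = 0.0431) and not without it (0.306). Camera gave an adjusted p = 0.21, and an adjusted p = 0.734 with an estimated correlation. At the preset correlation it called the list down on log2 TPM (adjusted p = 0.00922), without the ALDH- library of C29 (-0.57, adjusted p = 0.02) and without the ALDH+ library of C30 (-0.54, adjusted p = 0.00886). Its count was 3 without the ALDH- library of C30 and 2 without the ALDH+ library of C27 or C29, fits in which CCL4 reached up to 0.107. Of 24 apoptosis and p53 genes, the survival gene BCL2A1 fell (-3.94, adjusted p = 0.0022), 2 fell adjusted over the list alone, and with the block 1 rose and 3 fell. The macrophage list moved with the genes that fell here too, at -4.63. The apoptosis median was 0.18 (camera adjusted p = 0.55), and -0.6 with the scaling to fibroblast markers.

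Growth and housekeeping groups held few called genes. No member passed in edgeR among 35 measured DNA replication, 39 mitosis, 35 DNA repair, 30 glycolysis, 43 oxidative phosphorylation, 62 ribosomal protein and 13 mitochondrially encoded genes, either over all genes or adjusted over the list alone. At an unadjusted p under 0.05, the numbers higher and lower in ALDH+ were 0 and 2 for replication, 0 and 0 for mitosis, 1 and 2 for repair, 1 and 1 for glycolysis, 0 and 4 for oxidative phosphorylation, 0 and 0 for ribosomal proteins and 0 and 1 for mitochondrial transcripts. DESeq2 called 1 gene lower in each of replication, repair, glycolysis and oxidative phosphorylation and 0 in the other lists, and limma-voom called 0. Mitochondrial transcripts took 5.36, 8.6 and 17.3% of counts in the ALDH- libraries of C27, C29 and C30 and 3.22, 6.73 and 6.72% in the ALDH+ libraries. Their median was -1.21 (camera adjusted p = 0.00974, and adjusted p = 0.702 with an estimated correlation). The call ended without the ALDH- library of C30 (-0.40, adjusted p = 0.172) or the ALDH+ library of C27 (-0.66, adjusted p = 0.125), and with the block 2 fell, or 9 adjusted over the list alone. The oxidative phosphorylation median was -0.34 (adjusted p = 0.00229, and adjusted p = 0.702 with an estimated correlation), but 0.11 on log2 TPM, where it was not called (adjusted p = 0.117).

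The DNA replication (median -0.33, camera adjusted p = 0.0677) and mitosis lists (-0.34, adjusted p = 0.0516) were called with the block (adjusted p = 0.0146 and 0.025), with adjusted p = 0.773 and adjusted p = 0.781 with an estimated correlation. The median within a line was below 0 only in C29, at -1.56 for replication and -2.55 for mitosis, against 0.03 and 0.14 in C27 and 0.17 and 0.63 in C30. They were also called without the ALDH- library of C27 (-0.81 and -1.03, adjusted p = 0.000735 and 0.000688) or the ALDH+ library of C30 (-0.86 and -1.36, adjusted p = 4.5e-05 and 5.06e-08), with library size only (0.0494 and 0.0198) and with no filter on low counts (0.0382 and 0.0206). Mitosis was also called with DESeq2's size factors (adjusted p = 0.0368) and on log2 TPM (0.00895). The medians were -0.16 for DNA repair (camera adjusted p = 0.297), 0.05 for glycolysis (adjusted p = 0.55) and -0.01 for ribosomal proteins (adjusted p = 0.725). DNA repair was called without the ALDH+ library of C30 (-0.32, adjusted p = 0.00886), and ribosomal proteins without that of C29 (-0.30, adjusted p = 0.00433). On log2 TPM, which moved the median of all genes to 0.36, the medians turned to 0.07 for replication, 0.19 for repair and 0.37 for ribosomal proteins. The ribosomal median was 0.12 with library size only, which moved all genes by 0.17, and the glycolysis median was -0.84 with the scaling to fibroblast markers, where ribosomal proteins were called (-0.91, adjusted p = 0.0295).

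Of 36 measured immediate early and heat shock genes, the chaperone gene DNAJB1 (1.39, adjusted p = 0.0124) and HSPB9 (1.56, adjusted p = 0.0392) rose, 4 rose adjusted over the list alone and 6 with the block. Of 25 cholesterol synthesis genes, HMGCS1, from 37.6 ± 1.54 to 88.7 ± 17.1 CPM (n = 3; log2 1.24, SE 0.22, adjusted p = 0.0145), and MSMO1 (0.94, adjusted p = 0.0471) rose, 2 also adjusted over the list alone. With the block 2 cholesterol genes rose and INSIG1 (-1.10, adjusted p = 0.0231; without it -1.06 and 0.158), which restrains the pathway, fell. Of 24 unfolded protein response genes, the sensor kinase gene EIF2AK3 rose (1.07), with 0 in edgeR adjusted over the list alone (1 at an unadjusted p under 0.05, and 1 called over all genes by each of DESeq2 and limma-voom) and 2 with the block. Without the ALDH- library of C29 or C30, DNAJB1 (up to 0.0612) and HMGCS1 (up to 0.0692) lost their calls, as did HMGCS1 without the ALDH+ library of C27. HSPB9 stayed called only without the ALDH+ library of C27 (otherwise up to 0.137), and MSMO1 and EIF2AK3 only without the ALDH- library of C27 (up to 0.155 and 0.171). Camera gave a median of 0.40 and adjusted p = 0.00448 for heat shock (adjusted p = 0.505 with an estimated correlation), 0.30 and adjusted p = 0.0441 for cholesterol (adjusted p = 0.702 with an estimated correlation), and 0.12 and adjusted p = 0.297 for the unfolded protein response. The heat shock call ended without the ALDH+ library of C30 (0.37, adjusted p = 0.0702), and the cholesterol call with the block (adjusted p = 0.097), without the ALDH- library of C27 (0.15, adjusted p = 0.502) and without the ALDH+ library of C30 (0.15, adjusted p = 0.245). Scaled to fibroblast markers, which moves all genes down, the medians were -0.36, -0.61 and -0.77. The heat shock list was still called up (camera adjusted p = 0.00173), where camera compares the list with the other genes.

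Markers of other cells that ascites can hold had few called members. Of 8 measured endothelial markers, FLT1 rose (0.99, adjusted p = 0.0455) and PECAM1, which leukocytes also carry, fell (-2.98, adjusted p = 0.0069), with 3 rising and 1 falling both adjusted over the list alone and with the block. FLT1 lost its call without any 1 of the 6 libraries (up to 0.158). The endothelial median was 0.85 (camera adjusted p = 0.21). No mesothelial marker of 12 passed in edgeR or adjusted over the list alone, while 2 had an unadjusted p under 0.05, DESeq2 called 1 higher and limma-voom 0. With the block DES, LRRN4 and WT1 rose. The mesothelial median was 0.68 (camera adjusted p = 0.0296, and adjusted p = 0.505 with an estimated correlation), and the call ended without the ALDH- library of C30 (0.58, adjusted p = 0.127), without the ALDH+ library of C27 (0.51, adjusted p = 0.0614) and on log2 TPM (adjusted p = 0.0641). Of 10 granulosa and theca markers, the lipoprotein receptor gene VLDLR fell (-2.20, adjusted p = 0.0129), also adjusted over the list alone, and with the block 2 rose and 1 fell. VLDLR lost its call without the ALDH+ library of C27 or C29 (up to 0.0665). The granulosa list had a median of 0.33 (camera adjusted p = 0.812), and scaled to fibroblast markers the medians were -0.6 for granulosa and -0.13 for mesothelial markers.

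**Figure D2:**
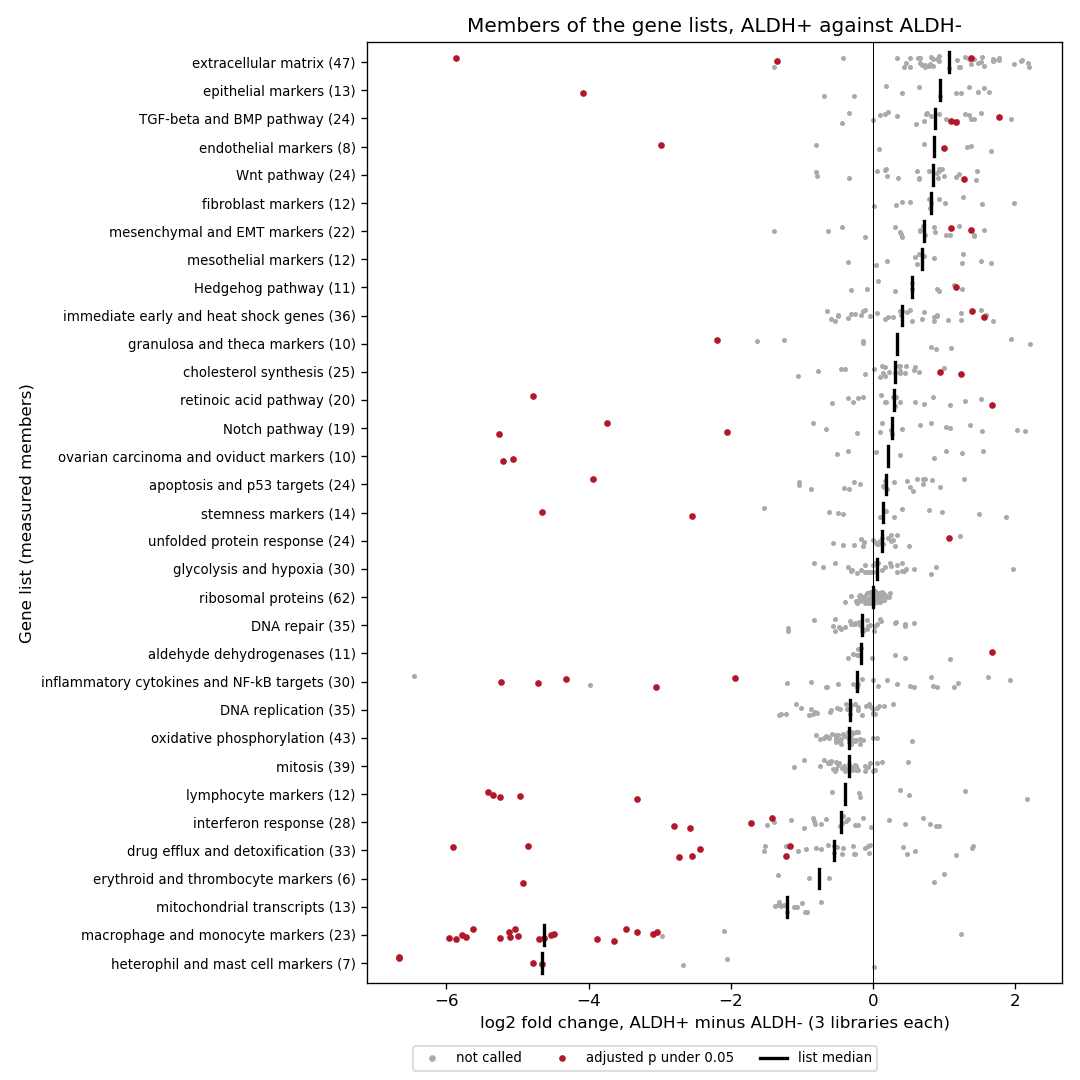
Log2 fold changes, ALDH+ minus ALDH- (x axis, 3 libraries each), of the measured members of 33 gene lists (y axis, number of members in brackets), in red where the adjusted p is under 0.05, with a black bar at each list's median. The macrophage and heterophil medians lie at -4.63 and -4.65 and matrix at 1.07 under TMM scaling. The medians of mesenchymal markers (0.72), Wnt (0.84) and TGF-beta (0.87) turn negative when scaled to fibroblast markers, which shifts the median of all genes to -0.84. Camera compares a list with the other genes, and its calls of these 3 lists stayed under that shift (adjusted p = 0.000164, 0.000493 and 2.86e-06). Under TMM scaling these calls are lost with an estimated correlation (camera adjusted p = 0.381, 0.24 and 0.381).

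The lines themselves were compared by an edgeR F test that took the fraction into account, which called 47 genes. The replicates of a line in this test were its ALDH- and ALDH+ libraries, sorted from the same culture. The errors and p values for lines therefore measure how line differences vary between the fractions, not between cultures of a line. Differences of a line cannot be told apart from those of its culture, because no line has a further culture here. In separate contrasts of single lines, C27 had 32 genes higher and 6 lower than the mean of the other lines, C30 had 24 higher and 53 lower, and C29 had 0 either way, with 1258 genes at an unadjusted p under 0.05 and no other tool run for single lines. In these contrasts, the genes highest in C27 were the chloride exchanger gene SLC26A3 (4.56, SE 0.36, adjusted p = 0.0183), CAPN6 (4.28), FAT3 (3.98), PLEKHS1 (3.75) and ADAMTS15 (3.71, SE 0.28, adjusted p = 0.0183). SLC26A3 stood at 56.3 and 53.9 CPM in the ALDH- and ALDH+ libraries of C27, 4.54 and 13.1 in C29, and 0.648 and 0.767 in C30. The genes highest in C30 were the chemokine gene CCL5 (7.70, SE 0.94, adjusted p = 0.0308), IL8L1 (6.02, SE 0.46, adjusted p = 0.0139), IL8 (3.94, adjusted p = 0.0276), the cytokine gene IL1B (3.59, SE 0.22, adjusted p = 0.00907) and HEPHL1 (3.12, adjusted p = 0.0258). In the F test over all lines CCL5 (adjusted p = 0.0543) and FAT3 (adjusted p = 0.0564) did not pass. Within C30, CCL5 stood at 350.5 CPM in ALDH- and 3.67 in ALDH+ cells, while IL8 stood at 1981 and 6089. The count of 47 became 1985, 1593, 476 and 272 without the ALDH- library of C29, the ALDH+ library of C29, the ALDH- library of C30 and the ALDH+ library of C30, and 77 without the ALDH+ library of C27. DESeq2 called 1209 genes and limma-voom 100.

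The comparison deposited by the authors was made on transcripts with DESeq2 and called 1864 of 25357 at a false discovery rate under 0.05, 644 higher and 1220 lower in ALDH+. The adjusted p deposited beside it was under 0.05 for 608 transcripts, and how either measure was made is not given in the sources used here. Across 12811 genes, log2 changes from edgeR and those of each gene's most abundant transcript in that table had a Spearman correlation of 0.977 and the same sign in 97.6%. Genes are not independent replicates, so no test goes with these values. Of the 786 genes called here, 766 (97.5%) had a transcript called there by the false discovery rate, where 95 would be shared by independent lists. For the blocked fit it was 1177 of 1732 genes.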

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

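The counts over other splits of the libraries were chosen before any result was seen, and the tests of scaling, RNA of other cells, exchanged labels, dilution and read assignment were chosen only after the results they test were seen.

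Outside the gene counts, 7 of 127 tested transcripts without a gene ID differed between the fractions (edgeR), and all 7 were lower in ALDH+ cells. In 6 of them the log2 change lay between -4.93 and -6.39, and the seventh had 14, 22 and 32 estimated counts in the ALDH- libraries of C27, C29 and C30 and 0 in each ALDH+ library.

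The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 786 genes and the highest of the others 137, so 1 of the 10 splits gave as many. That other split set both libraries of C27 and the ALDH+ library of C29 against the rest and had 2797 genes at an unadjusted p under 0.05, against 2637 in the real split. For gene lists the real split gave 16 and the highest other 14 (1 of 10 splits as many). With the line as a block, 4 splits part every pair of libraries, again too few, with 1732 genes in the real split and 0 in edgeR in the others (11 to 165 genes at an unadjusted p under 0.05), so 1 of the 4 gave as many. DESeq2 and limma-voom were not run on other splits.

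Macrophage and monocyte markers were far lower in ALDH+ cells in each line, with list medians of -4.31 (C27), -4.01 (C29) and -5.70 (C30). The scaling of the libraries is argued against, since the list median nearest to 0 over the scalings run was -3.66 (log2 TPM) while the median of all genes moved by at most -0.84. A pair of libraries with exchanged labels is argued against by a list median below 0 in 3 of 3 lines. RNA of macrophages in the ALDH- fraction and a different state of tumour cells with low ALDH activity both stay open and cannot be told apart, because the 20 of 23 members more than 4-fold lower in the line with the fewest are the pattern itself and would follow from either. The most abundant member, MARCO, stood at 2474 CPM in ALDH- cells, the labels name no gate but ALDH activity, 21 of the 23 members also had a mean of at least 1 CPM in ALDH+ cells, and 1 member is in another list.

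Genes higher in ALDH+ could come from dilution, if other cells supply part of the ALDH- RNA and lower the share of all tumour cell transcripts there. When the libraries were scaled to the fibroblast marker list, 28 of the 107 genes were still called higher, with a median log2 change of 2.22 (SE 0.42) before and 1.37 (SE 0.42) after, VCL among them (1.42, adjusted p = 0.00898 in edgeR). For the other 79 genes the call ended, with a median of 1.43 (SE 0.3) before and 0.58 (SE 0.29) after. The scaling lowers all genes by a like amount, so which calls ended depended on the size and error of the change before it. Dilution and a higher level in ALDH+ cells cannot be told apart for either set, since the scaling takes fibroblast markers as equal in the tumour cells of both fractions, which was not tested, and the 28 are genes picked because they still passed. With the line as a block, 149 of the 758 higher genes stayed called.

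Some transcripts were counted in all 3 libraries of 1 fraction (at least 10 counts each) and in none of the other (under 1), at a gene total within 2-fold, 17 in ALDH+ and 8 in ALDH- cells. In the deposited table a MYO9B transcript had a log2 change of 11.4 while the gene stood at -0.11 (adjusted p = 0.88 in edgeR), and a CTBP1 transcript 9 against 0.22 (0.684), both chosen after their values were seen. An assignment of reads among transcripts of 1 gene, unrelated to the fraction, may account for them, since 2 of 10 splits gave as many such transcripts in either direction, the real one with 25 and the highest other with 36. Among the 20 ways to take 3 libraries, another set (both libraries of C27 and the ALDH+ library of C30) had 29 such transcripts against 17 for ALDH+. A different use of transcripts in the fractions stays open for the 17, since few splits exist.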

How the results depend on the processing

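The scaling to fibroblast markers and the counts on transcripts were chosen after the data were examined, and the other alternatives before. Of 786 genes without the block, each alternative kept the count within 1.5 times except these, where the cause was not tested unless stated. DESeq2 called 1655 genes (626 higher, 1029 lower in ALDH+), the block 1732, the block with DESeq2 2612 (1366 and 1246), and the block with limma-voom 1917 (849 and 1068). Scaling to fibroblast markers gave 5786 (33 and 5753), because it moves all genes down. Without 1 library the count ran from 443 to 1123, with fewer samples in each fit.

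For the blocked count of 1732, DESeq2 gave 2612, limma 3146 (2392 and 754) on log2(TPM + 1) and 3101 (2349 and 752) on log2(TPM + 0.1), transcripts 407 (68 and 339) and fibroblast scaling 7308 (149 and 7159). Leaving out a library or a line gave 1010 to 2447, with 1010 (311 and 699) without C27 and 1143 without the ALDH+ library of C30.

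The 47 genes among lines became 7 with DESeq2's size factors, 80 with upper quartile factors, 419 with library size only, 269 with no filter, 3 with a mean CPM of at least 5, 1209 with DESeq2, 100 with limma-voom, 1086 and 1041 on log2(TPM + 1) and log2(TPM + 0.1), and 0 in limma on log2(TPM + 1) with no filter, where 2600 genes had an unadjusted p under 0.05. Without 1 library it ran from 45 to 1985.

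Of the 16 gene lists called (9 up, 7 down), 0 passed with an estimated correlation in camera (3 at an unadjusted p under 0.05), and 0 with the block and an estimated correlation (0 at an unadjusted p under 0.05). Fry called 8 (2 up, 6 down), 7 of them among the 16. The other was the ovarian carcinoma and oviduct list (down, adjusted p = 0.0112). With the block fry called 2, Wnt up and inflammatory genes down (adjusted p = 0.0431 each). In camera the block called 18, losing cholesterol synthesis (adjusted p = 0.097) and gaining DNA replication (0.0146), epithelial markers (0.0141) and mitosis (0.025), and changed no other list call. Scaling to fibroblast markers ended the calls of cholesterol synthesis (0.334), interferon (0.0716), lymphocyte (0.196) and mitochondrial genes (0.296) and added epithelial markers (0.00101) and ribosomal proteins (0.0295). With no filter, the calls of cholesterol synthesis (0.0607) and mesothelial markers (0.0719) ended and DNA replication (0.0382) and mitosis (0.0206) were added. Log2 TPM ended oxidative phosphorylation (0.117) and mesothelial markers (0.0641) and added mitosis (0.00895) and inflammatory genes (0.00922), size factors added mitosis (0.0368), and library size only added DNA replication (0.0494) and mitosis (0.0198). Leaving out libraries or lines gave 13 to 20 lists. On log2 TPM the medians of called lists moved by over 1.5 times for mesenchymal (1.16), fibroblast (1.33), heat shock (0.8), cholesterol (0.66), mesothelial (1.07), lymphocyte (-1.47), detoxification (-0.16), interferon (-0.01), oxidative phosphorylation (0.11) and mitochondrial genes (-0.66). With library size only, medians moved as far for oxidative phosphorylation (-0.14), interferon (-0.26), detoxification (-0.36), heat shock (0.65) and Hedgehog genes (0.86). With no filter they did for lymphocyte (-0.15) and heterophil markers (-2.08).

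Of the 68 called among 146 named genes, the block kept 68 and added 42, size factors kept 66, upper quartile factors 66, library size only 65, DESeq2 67 of 67, limma-voom 61, log2(TPM + 1) 59 of 63 and, with no filter, 50, and fibroblast scaling 55, and leaving out a library kept 38 to 60. None of the named genes or lists was called in opposite directions under the alternatives run for them. The directions of the other genes were not compared under each alternative. The Spearman correlation with the deposited log2 changes was 0.977, and 0.955 to 1 under the alternatives. With 3 libraries a group, 2-fold changes could mostly not be called, and genes with few counts in ALDH+ cells, such as MFNG (179 against 5 counts), have imprecise folds.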

Other observations

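The lists of adhesion and of lysosome genes, the medians by line and the genes with opposite lines were all chosen after the data were examined, so they are not independent evidence. The adhesion list was written after VCL, ITGA8, ITGA9 and PDLIM3 had been seen among the genes that rose most. Some genes of focal adhesions and the actin cytoskeleton rose in ALDH+ cells, beside the macrophage markers at a median of -4.63. Of 51 measured members 9 rose, 32 rose and 1 fell adjusted over the list alone, and 24 rose with the line as a block. Besides VCL, ITGA8, ITGA9 and PDLIM3, these included the actin regulator gene ENAH, from 85.8 ± 12.3 to 245.1 ± 58.4 CPM (n = 3; log2 1.51, SE 0.25, adjusted p = 0.0113 in edgeR), the caldesmon gene CALD1 (1.59, adjusted p = 0.0179), LIMS2 (1.69, adjusted p = 0.0266) and ACTA1 (1.79, adjusted p = 0.0414), whose reads are hard to tell from those of other actins. The list took 2.11, 1.75 and 1.37% of counts in the ALDH- libraries of C27, C29 and C30 and 3.55, 3.74 and 3.79% in the ALDH+ libraries. Its median was 0.99 and stayed above 0 in each scaling run, from 1.35 on log2 TPM to 0.14 when scaled to fibroblast markers. Camera gave an adjusted p = 0.0172 with an estimated correlation and an adjusted p = 0.0753 with the block and an estimated correlation. Without the ALDH+ library of C27 or C29 the estimated-correlation values were 0.0505 and 0.0563, and the number of genes that rose was 15, 1 and 2 without the ALDH- library of C27, C29 or C30 and 4 and 5 without the ALDH+ library of C27 or C29.

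Many but not all lysosome and vacuolar ATPase genes were lower in ALDH+ cells, beside the macrophage markers at a median of -4.63. Of 59 measured members 31 fell, 42 adjusted over the list alone. Cathepsin D (CTSD) fell from 8547 ± 4860 to 517.3 ± 186 CPM (n = 3; log2 -4.05, SE 0.61, adjusted p = 0.00658 in edgeR), the glucuronidase gene GUSB by 2.49 on the log2 scale (-2.49, adjusted p = 0.00174), LAMP1 by 1.65 (-1.65, adjusted p = 0.0124) and the proton pump subunit gene ATP6V0D2, known from osteoclasts and macrophages, by 5.36 (-5.36, adjusted p = 0.0011). The list took 2.73, 3.33 and 3.43% of counts in ALDH- and 1.12, 1 and 0.75% in ALDH+ cells of C27, C29 and C30. The median was -1.19, and from -0.72 on log2 TPM to -2.04 when scaled to fibroblast markers. Camera gave an adjusted p = 0.0354 with an estimated correlation and an adjusted p = 0.191 with the block and an estimated correlation. Without the block, the value with an estimated correlation was 0.103 and 0.0595 without the ALDH- library of C27 or C29 and 0.0505 and 0.0563 without the ALDH+ library of C27 or C29. The number that fell was 18 and 13 without the ALDH- library of C29 or C30 and 13 and 17 without the ALDH+ library of C27 or C29.

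The list medians of mitosis genes differed in sign between the lines, although no single mitosis gene passed between the fractions. Their median log2 difference, ALDH+ minus ALDH-, was 0.14 in C27, -2.55 in C29 and 0.63 in C30, and for DNA replication genes it was 0.03, -1.56 and 0.17. Mitosis genes took 0.272% of counts in ALDH- and 0.0602% in ALDH+ cells of C29, and 0.168 and 0.317% in C30. With 1 library per line and fraction the difference between lines was not tested.

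Of the 12811 genes tested, 174 (1.4%) had a difference of at least 1 on the log2 scale upward in some line and downward in another.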
